A study of Bos taurus with 6 samples.

How the data were processed

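The study measured polyadenylated RNA in individual bovine (Bos taurus) oocytes at 2 stages. GV (germinal vesicle) oocytes are arrested in meiotic prophase and were collected at aspiration of follicles. MII oocytes had been matured in vitro for 24 hours and had reached metaphase of the second meiotic division. Per the labels, cDNA was primed on poly(A) tails and amplified with a kit for very low RNA input, and the libraries were read as single Illumina reads. The authors diluted the library adapters differently among samples, per the labels, from 1 in 10 to 1 in 30 for GV and from 1 in 30 to 1 in 50 for MII.

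The authors deposited a table of RPKM, reads scaled to the length of the gene model and to the mapped reads of the library, for 20707 Ensembl genes in 6 libraries, per the file headers. The submitters' processing notes name DESeq, and the role it played, the aligner, the counting tool and the genome build are not given in the sources used here. The authors deposited a second file with gene, transcript and coding coordinates, extended by transcript discovery on their reads, per the file headers. Coordinates printed here are those of that annotation, counted from 1, and its build is likewise not given in the sources used here. Gene symbols are the human ortholog names that the RPKM table pairs with each Ensembl identifier. Of these, 390 were missing and 27 had turned into whole numbers, so 417 genes had no usable symbol.

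The columns of the table are GV14, GV14c, GV15, MII14c, MII15 and MII15c. The sample titles are GV14, GV15, GV15c, MII14, MII14c and MII15. No title reads GV14c or MII15c, so those 2 columns were used as a GV and an MII library with no label of their own beyond the stage. Stage was taken from the titles, since another label calls all 6 samples matured in vitro. What the numbers 14 and 15 and the letter c stand for is not stated, and nothing says whether the oocytes came from different animals, so p-values measure the spread between these libraries only. It is likewise not stated whether a column with the letter c is a further oocyte or a repeat of the one of the same number, so n = 3 counts libraries, and p-values are too small if some are repeats. Spearman's rho was 0.921 for GV14 with GV14c and 0.95 with GV15, and 0.921 for MII15c with MII15 and 0.965 with MII14c.

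Depth was recovered from the low RPKM values. For 3452 genes whose model is coding sequence alone, RPKM is a whole number of reads divided by a known length and by depth, and the depth that made low values whole was found for each library. It came to 29.93, 26.91 and 20.2 M reads for GV14, GV14c and GV15, and to 31.13, 21.27 and 32.55 M for MII14c, MII15 and MII15c. At those depths 97.9% to 99.6% of the low values were within 0.1 of a whole read. For a gene model of 2 kb, 1 RPKM is 40.4 to 65.1 reads. Amplified reads without molecular identifiers are not independent molecules, so this describes counting error only.

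Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 8671 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(RPKM + 1), MII against GV, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 change is on that scale, MII minus GV, and understates the change of low genes. A change is relative to the total of mapped reads in a library, since no spike-in or cell count enters the values. RPKM are not read counts, so no count model was run. The test was tried on simulated data made for the same 8671 genes. It recovered 5% of genes changed 2-fold and 51% of genes changed by 2 on the log2 scale, and 5.1% of its calls were false. Only 100 genes were changed at each size, whereas 40.3% of tested genes were called in the data. The adjustment was therefore stricter in the simulation, and the recovered shares do not give the power reached here.

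The lists of genes, 24 in number, the rule for naming genes and the processing alternatives were written before the data were examined. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over the 22 lists with at least 3 tested members. Under the alternatives, camera was run on limma's moderated t. The rule named the 12 largest rises and 12 largest falls past the threshold with at least 10 RPKM in the higher stage and no overlap between stages, up to 4 members of smallest p from each list, 16 genes fixed in advance, and the 3 most abundant genes of each stage. Members that make up a list's count of 5 or fewer rises or falls in the fit as planned are named as well, and those outside the rule were chosen after their values were seen. Values of 1 gene that the rule names are not reported here. Where several rows carry a symbol, the row of highest mean RPKM stands for it in the lists and among the fixed genes. Among the 12 rises and 12 falls, the row with the largest change that met the rule stands for it. The most abundant genes were taken row by row. Reads of such a row may be shared with the others of its symbol. Such sharing may affect NLRP7, NPR2 and POU5F1, with 2 rows each, and the genes whose number of copies is given beside them.

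The distance called the 3' UTR distance here is a number of nucleotides on the genome, with a minimum of 50 nt. It runs from the end of the gene's longest coding sequence to the farthest end among its transcripts. It can include introns, because transcripts are given by start and end alone. It can also include coding exons of another isoform that codes farther downstream. Medians were compared with two-sided permutation tests of 100000 resamples in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Intervals of medians are 95% bootstrap intervals from 2000 draws. The permutation test was tried on simulated distances with and without a known shift. Detected genes were compared with an exact two-sided permutation test.

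Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter, a mean of at least 5 RPKM, scaling by median ratios, by quantiles or to TPM, a fixed total per library, no mean-variance trend, weights per library, a block for the title number, and leaving out each library. Sequence motifs of 3' UTRs, such as cytoplasmic polyadenylation elements, need a genome sequence and were not analysed here. Transcripts encoded by the mitochondrial genome were on 1 of the lists and had no rows in the table used here.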

Results

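The data are gene-level RPKM of 3 GV and 3 MII libraries of bovine oocytes, with 20.2 to 29.93 M reads per GV library and 21.27 to 32.55 M per MII library. The comparison asks which mRNAs differ in measured abundance between the prophase-arrested oocyte and the oocyte matured to metaphase II. The study's title ties this to cytoplasmic polyadenylation, the lengthening of poly(A) tails outside the nucleus. Library preparation was primed on poly(A) tails, so a measured level combines the number of transcripts with how well their tails were captured.

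The MII libraries held fewer detected genes than the GV libraries. At 1 RPKM or more, GV libraries held 8831, 9304 and 8401 genes (mean 8845 ± 452, SD, n = 3) and MII libraries 8087, 7170 and 7760 (7672 ± 465, SD, n = 3). Every GV library lay above every MII library, and the exact permutation p was 0.1, the smallest that 3 against 3 allows. BTG4, an antiproliferative factor that brings deadenylases to maternal mRNA, was the most abundant mRNA of MII at 20430 ± 6470 RPKM, against 11050 ± 2790 in GV (SD, n = 3). UBB, a polyubiquitin gene, was the most abundant of GV at 12360 ± 2850 RPKM and fell to 4553 ± 1120 in MII (log2 change -1.45 ± 0.27, SE; limma adjusted p = 0.00333). PTTG1, the securin that inhibits separase until anaphase, rose from 4825 ± 886 to 8804 ± 1460 RPKM (log2 change 0.87 ± 0.24, SE; limma adjusted p = 0.0201), although 3 genes carry its symbol. The gene ENSBTAG00000038488, which the annotation names after thymosin beta 4, rose from 7140 ± 1540 to 13040 ± 3640 RPKM (limma adjusted p = 0.0448). For the 3 of these that rose the error was large against the change. The call was lost under 9 of 18 alternatives for BTG4 (limma adjusted p = 0.0488; 0.0031 to 0.364 over the alternatives), including without GV14, GV14c, MII15 or MII15c. Those adjusted p-values were 0.132, 0.135, 0.137 and 0.134. The call was lost under 6 alternatives for PTTG1 (adjusted p = 0.0783, 0.0537 and 0.0826 without GV14, MII15 or MII15c; 0.000451 to 0.198 over the alternatives). It was lost under 8 for ENSBTAG00000038488 (0.155, 0.0829, 0.103 and 0.181 without GV14, GV15, MII15 or MII15c; 0.000453 to 0.3 over the alternatives), and under 2 for UBB, median-ratio scaling and no filter (0.0735 and 0.071; 1.63e-05 to 0.0735 over the alternatives).

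Across the transcriptome, 2329 of 8671 tested genes were lower and 1162 higher in MII than in GV (limma, adjusted p under 0.05). Of these, 2137 were at least 2-fold lower and 687 at least 2-fold higher. The stages did not overlap in 51.9% of tested genes, where chance gives 10%, with 2786 lower and 1715 higher in MII. The first principal component held 69.9% of the variance and separated the stages. The split between lower and higher depends on scaling. Genes called lower made up 66.7% of calls as deposited, 55% after median-ratio scaling, 45.4% after quantile normalization and 59.9% after TPM scaling. Among changes of at least 2-fold the shares were 75.7%, 58.6%, 49.5% and 65.1%. The median log2 change of all tested genes was -0.16 as deposited, 0.05, 0.22 and -0.07 under those scalings, and medians of lists called by camera are also given relative to it. The count of higher genes was 762 without GV14, 761 without GV15 and 585 without MII15c. Without both columns that match no title, GV14c and MII15c, 352 genes were higher and 1280 lower, a fit added after seeing the data. On the second component, with 17% of the variance, the libraries whose name ends in c (1 GV, 2 MII) lay apart from the others, and with that letter as a term beside the stage, a model added after seeing the data, 1468 genes were higher and 2975 lower. The labels give adapter dilutions of 1 in 30 and 1 in 10 for GV14 and GV15 and of 1 in 50 for MII14c and MII15, so dilution and stage cannot be told apart.

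**Figure D1:**
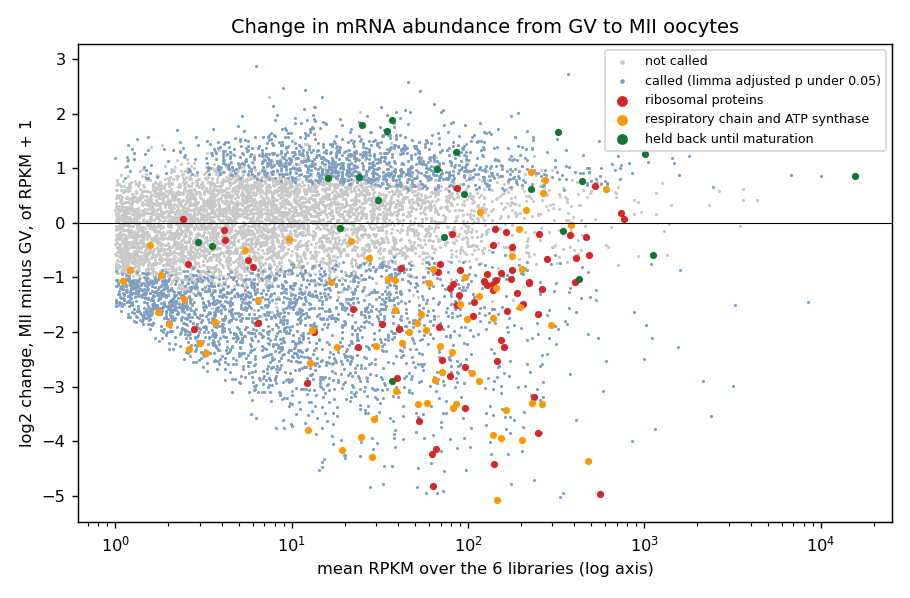
Log2 change from GV to MII (MII minus GV, RPKM + 1) against mean RPKM over the 6 libraries on a log axis, 1 point per tested gene; blue points passed the limma threshold and grey points did not. Ribosomal protein (red) and respiratory chain (orange) genes lie mostly below 0, with medians of -1.13 and -1.84, and mRNAs described as held back until maturation (green) mostly above it, with a median of 0.69.

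The 12 steepest falls started from GV means of 54.3 to 1084 RPKM. NDUFA8, a subunit of respiratory complex I, fell from 284 ± 96.8 to 7.52 ± 3.40 RPKM (SD, n = 3 per stage; log2 change -5.08 ± 0.33, SE; limma adjusted p = 2.13e-05). CNIH4, a cargo receptor of the early secretory pathway, fell from 641.6 ± 57.2 to 18.97 ± 4.93 RPKM (log2 change -5.03 ± 0.23). FAU, which encodes a ubiquitin-like protein fused to ribosomal protein S30, fell from 1084 ± 84.3 to 34.27 ± 8.55 RPKM (log2 change -4.97 ± 0.22). POLR2G, a subunit of RNA polymerase II, fell from 671.3 ± 103 to 20.92 ± 4.94 RPKM. NHP2, a core protein of small nucleolar ribonucleoproteins, fell from 112.3 ± 17.5 to 2.88 ± 1.64 RPKM. EXOSC1, a subunit of the RNA exosome, fell from 99.52 ± 17.7 to 3.025 ± 2.23 RPKM. C19orf70, a component of the mitochondrial cristae organizing complex, LAMTOR2, a lysosomal scaffold of nutrient signalling, DDX39A, an RNA helicase of mRNA export, DPCD and FKBP2, a prolyl isomerase of the endoplasmic reticulum, also fell (log2 changes -4.96, -4.91, -4.84, -4.78 and -4.78). RPL6 fell as well (log2 change -4.82), but 4 genes of the table carry that symbol, so its reads may be shared, as may those of FAU and FKBP2, with 2 each. Limma adjusted p-values of these 12 genes lay between 4.87e-06 and 0.000145, and all 12 kept the call under all 18 alternatives. In the annotation NDUFA8 lies on chromosome 11 from 93011812 to 93029730 with 4 coding exons, CNIH4 on chromosome 16 from 28231307 to 28248345 with 5, and FAU on chromosome 29 from 43989947 to 43991956 with 6.

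Components of the respiratory chain and of the ribosome were lower together. Of 73 tested genes for nuclear-encoded respiratory chain and ATP synthase subunits, 55 fell, 4 rose and 14 did not pass the test, with a median log2 change of -1.84 (-1.67 relative to all genes, and -1.79 to -1.65 under the 3 other scalings). There were 59 lower when adjusted over the list alone. COX6A1 fell from 912.3 ± 84.6 to 43.52 ± 5.41 RPKM (SD, n = 3; log2 change -4.36 ± 0.19, SE; limma adjusted p = 4.87e-06), and ATP5G1, NDUFB9 and COX7A2 fell too (log2 changes -3.99, -3.89 and -3.42). The 4 that rose were NDUFB6, UQCRH, ATP5F1 and ATP5J (log2 changes 0.79, 0.55, 0.92 and 0.63), named after their values were seen, and 1 to 2 rose without GV14, GV15, MII15 or MII15c. Of 73 tested ribosomal protein genes, 42 fell, RPS3 rose and 30 did not pass, with a median of -1.13 (-0.97 relative to all genes, -1.19 to -0.90 under the other scalings). Adjusted over the list alone, 43 were lower. RPL34 fell from 99.12 ± 31.6 to 6.917 ± 1.65 RPKM (log2 change -3.63 ± 0.29; limma adjusted p = 4.45e-05) and RPL7 from 176.5 ± 26.2 to 16.09 ± 3.81 RPKM (-3.39 ± 0.24), while RPS3, named after its value was seen, rose from 406.3 ± 87.3 to 637.3 ± 33.1 RPKM (0.67 ± 0.21; limma adjusted p = 0.0337). No ribosomal protein gene passed as higher in limma without GV14, GV15, MII14c or MII15c. Several genes carry the symbols RPL7 (9), RPL34 (2) and COX6A1 (2), so their reads may be shared. Both lists passed camera with a preset correlation (limma's camera, adjusted p = 1.65e-12 for the respiratory chain and 2.14e-07 for ribosomal proteins). The correlation between members was estimated at 0.131 and 0.55, above the preset 0.01. With an estimated correlation neither list passed (adjusted p = 0.42 and adjusted p = 0.683 with an estimated correlation).

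**Figure D2:**
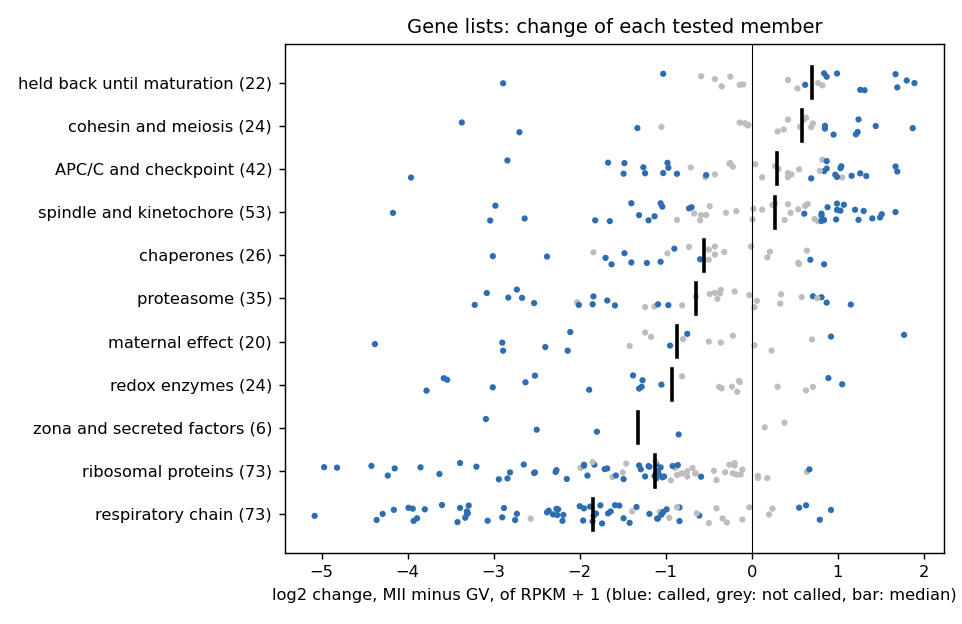
Log2 change from GV to MII (MII minus GV, RPKM + 1) of each tested member of 11 gene lists, with the number tested in parentheses; blue points passed the limma threshold, grey points did not, and black bars are medians. The medians run from -1.84 for the respiratory chain to 0.69 for mRNAs held back until maturation, and each of the 11 lists holds members on both sides of 0.

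The largest rises were smaller than the largest falls. CASC4, a Golgi membrane protein, rose from 0.669 ± 0.235 to 11.82 ± 5.01 RPKM (SD, n = 3; log2 change 2.88 ± 0.36, SE; limma adjusted p = 0.000416). DBT, a subunit of the branched-chain ketoacid dehydrogenase, rose from 16.24 ± 2.42 to 90.17 ± 6.27 RPKM (2.41 ± 0.22). TOP2B, a DNA topoisomerase, rose from 27.21 ± 4.56 to 117.5 ± 22.4 RPKM (2.07 ± 0.23), and CEP120, a centriole elongation protein, from 16.27 ± 2.65 to 71.47 ± 13.0 RPKM (2.07 ± 0.24). RAP2C, a small GTPase, GAR1, a small nucleolar ribonucleoprotein component, PTAR1, CSGALNACT2, an enzyme of chondroitin sulfate synthesis, FAM76B and ACBD5, a peroxisomal tether, also rose (log2 changes 2.30, 2.19, 2.14, 2.12, 2.12 and 2.09), with 2 genes under the symbol RAP2C. Rows with the symbols TMSB4X, an actin-binding peptide, and WTAP, a component of the mRNA methylation complex, rose by 2.72 and 2.43 on the log2 scale. Each has no name and 1 coding exon in the annotation, of 135 and 453 nt, and shares its symbol with other genes (5 carry TMSB4X, 3 carry WTAP). The abundant ENSBTAG00000038488, which carries the same thymosin name, has 3 coding exons and 189 nt. Reads may be shared between copies. Each of the 2 rows is the copy with the largest change that met the rule. It is therefore not shown that the genes encoding these 2 proteins rose this much. Limma adjusted p-values of the 12 rises were 7.91e-05 to 0.0157. The call of ACBD5 was lost without GV14, MII14c or MII15c (adjusted p = 0.0605, 0.053 and 0.071; 1.39e-05 to 0.071 over the alternatives). CASC4 lies on chromosome 10 from 103802803 to 103891476 with 9 coding exons in the annotation, and DBT on chromosome 3 from 43189864 to 43230456 with 11.

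Among mRNAs described in frog, mouse or cattle oocytes as stored and then polyadenylated in maturation, more rose than fell. Of 22 tested, 10 rose, CCNB2 and ZAR1 fell, and 10 did not pass, with a median log2 change of 0.69 (0.86 relative to all genes, 0.55 to 0.92 under the other scalings). Adjusted over the list alone, 11 were higher and 3 lower. CCNB1, the cyclin that activates CDK1 for entry into M phase, rose from 592 ± 77.4 to 1418 ± 159 RPKM (SD, n = 3; log2 change 1.26 ± 0.20, SE; limma adjusted p = 0.00145), although 3 genes carry its symbol. WEE2, an oocyte kinase that inhibits CDK1, rose from 153.8 ± 30.5 to 492.1 ± 92.3 RPKM (1.67 ± 0.23). CPEB4, which binds cytoplasmic polyadenylation elements, rose from 10.63 ± 1.46 to 39.38 ± 1.57 RPKM (1.80 ± 0.23), and FBXO43, an inhibitor of the anaphase-promoting complex, from 15.88 ± 1.40 to 53.78 ± 9.51 RPKM (1.69 ± 0.23). CCNB2, the other B-type cyclin, fell from 569.7 ± 47.9 to 282.5 ± 55 RPKM (-1.03 ± 0.21; limma adjusted p = 0.00508), a call that was lost with median-ratio scaling (adjusted p = 0.0852; 4.47e-05 to 0.0852 over the alternatives). AURKA went from 1356 ± 332 to 888.7 ± 67.2 RPKM (adjusted p = 0.0643), MOS from 4.331 ± 2.75 to 2.765 ± 1.15, CDC20 from 10.66 ± 6.60 to 21.62 ± 16 and DAZL from 83.96 ± 61.5 to 105.5 ± 28.4, and none of these passed limma's test. DAZL passed without GV14 (adjusted p = 0.0323) and with the letter c as a term (0.0496; 0.0323 to 0.853 over the alternatives), AURKA with library weights (0.0102) and the letter c (0.0152; 0.0102 to 0.44), and CDC20 with library weights (0.0034; 0.0034 to 0.805). PLAT, at 0.902 RPKM in GV and 0.0817 in MII, was below the level tested. The list passed camera (adjusted p = 0.0127; 0.0076 to 0.0514 over the alternatives, and 0.0514 with a mean of at least 5 RPKM), and did not with an estimated correlation (adjusted p = 0.42 with an estimated correlation).

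**Figure D3:**
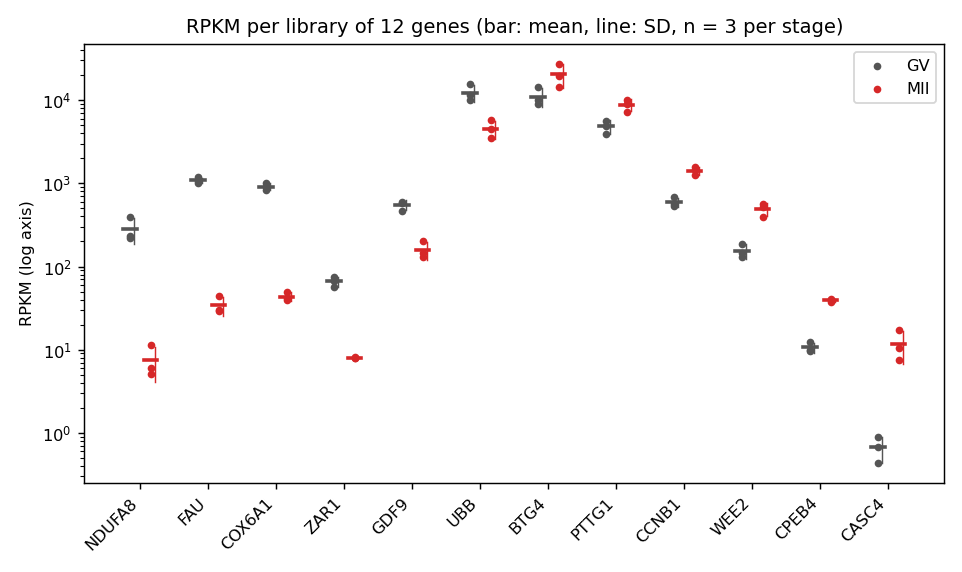
RPKM on a log axis of 12 genes in each of the 3 GV (grey) and 3 MII (red) libraries; horizontal bars are means and vertical lines SDs. NDUFA8, FAU, COX6A1, ZAR1, GDF9 and UBB are lower in every MII library than in any GV library, and the other 6, from BTG4 (11050 to 20430 RPKM) to CASC4 (0.669 to 11.82 RPKM), are higher.

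Meiotic chromosome genes moved in both directions. Of 24 tested cohesin and meiotic prophase genes, 8 rose, 3 fell and 13 did not pass, with a median log2 change of 0.58 (0.74 relative to all genes, 0.63 to 0.80 under the other scalings). The counts were the same adjusted over the list alone. STAG1 and SMC3, subunits of cohesin, rose from 5.197 ± 0.875 to 21.85 ± 5 and from 103.9 ± 5.63 to 245.3 ± 26.4 RPKM (log2 changes 1.87 ± 0.28 and 1.23 ± 0.19, SE; limma adjusted p = 0.0011 and 0.00123). SYCE2, a synaptonemal complex protein, fell from 97.74 ± 47.9 to 13.72 ± 4.98 RPKM (-2.70 ± 0.37), and HORMAD2, a meiotic axis protein named after its value was seen, from 2.566 ± 1.05 to 0.388 ± 0.230 RPKM. The list passed camera as planned (adjusted p = 0.0307), but not on limma's moderated t (adjusted p = 0.0779), the form used for the alternatives, where it passed under 2 of them, no filter and without GV15 (0.0436 and 0.0398; 0.0398 to 0.18 over the alternatives). It did not pass with an estimated correlation either (adjusted p = 0.683 with an estimated correlation), nor in fry (fry adjusted p = 0.13). Of 53 tested spindle and kinetochore genes, 18 rose and 14 fell. ECT2, the guanine nucleotide exchange factor of cytokinesis, rose from 36.4 ± 6.06 to 117 ± 6.64 RPKM (1.67 ± 0.21), whereas TUBA1B and TUBB4B, which encode tubulins, and SPC24, of the NDC80 complex, fell (log2 changes -4.17, -2.98 and -2.64), with 2 genes under the symbol TUBA1B. Without MII15c, 11 rose and 9 fell, and 8 and 9 fell after median-ratio and quantile scaling. Of 42 tested genes of the anaphase-promoting complex and the spindle checkpoint, 13 rose (8 without MII15c) and 12 fell (7 and 8 after median-ratio and quantile scaling, with 14 and 16 higher), among the latter MAD2L2 (-3.96 ± 0.44), ANAPC13 (-2.84 ± 0.21) and ANAPC10 (-1.49 ± 0.20). Adjusted over the list alone, 19 spindle genes were higher and 17 lower, and the checkpoint counts were the same. Neither list passed camera (adjusted p = 0.141 and 0.184). Medians of 0.27 and 0.29 against means of -0.08 and -0.03 show long lower tails in both.

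Zona, oocyte-secreted factor and maternal-effect mRNAs were mostly lower or not called. All 4 changes among 6 tested zona pellucida and oocyte-secreted factor genes were falls. ZP4 fell from 1701 ± 539 to 296.7 ± 71.3 RPKM (SD, n = 3; log2 change -2.50 ± 0.28, SE; limma adjusted p = 0.000229) and GDF9, a growth factor that acts on cumulus cells, from 551.1 ± 75.9 to 159.8 ± 39.7 RPKM (-1.80 ± 0.23; adjusted p = 0.000504). ZP3 fell from 1055 ± 1070 to 109.8 ± 77.3 RPKM (-3.09 ± 0.85; adjusted p = 0.0184), and without GV14c the call was lost (adjusted p = 0.0506; 7.91e-07 to 0.0782 over the alternatives). ZP2 fell by 0.85 on the log2 scale, a call lost without GV15, MII14c or MII15c (adjusted p = 0.0766, 0.0582 and 0.111; 0.000201 to 0.256 over the alternatives). BMP15, the partner of GDF9, was at 792 ± 67.1 and 1060 ± 328 RPKM and did not pass (adjusted p = 0.245). Of 20 tested maternal-effect genes, 8 fell, 2, YAP1 and KPNA7, rose, and 10 did not pass, with a median of -0.87. FIGLA, a transcription factor of the zona genes, fell from 29.05 ± 6.01 to 0.477 ± 0.506 RPKM (-4.38 ± 0.34; adjusted p = 3.88e-05), ZAR1 from 66.31 ± 8.93 to 8.022 ± 0.104 RPKM (-2.89 ± 0.22). NLRP2, NLRP7 and NLRP5, the last of the subcortical maternal complex, also fell (log2 changes -2.90, -2.40 and -2.14), as did NPM2, an oocyte histone chaperone, from 1779 ± 132 to 437.8 ± 171 RPKM (-2.11 ± 0.31). YAP1 and KPNA7 were named after their values were seen, and 1 maternal-effect gene rose without GV14, GV15, MII14c or MII15c. The counts of both lists were the same adjusted over the list alone. Camera as planned called neither list (adjusted p = 0.195 and 0.11). Under the alternatives the zona list passed in 1, the replicate block (0.0402; 0.0402 to 0.382 over the alternatives), and the maternal-effect list in 6, among them without GV15 or MII14c (0.0317 and 0.0285; 0.0285 to 0.112 over the alternatives). With an estimated correlation neither passed (adjusted p = 0.683 and adjusted p = 0.722 with an estimated correlation). Fry, which does not compare members with other genes, called both lists as lower (fry adjusted p = 0.018 and 0.0497).

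Enzymes of redox defence, the proteasome and chaperones fell more often than they rose, though camera as planned called none of these lists (adjusted p = 0.11, 0.11 and 0.184). On limma's moderated t the redox list passed (adjusted p = 0.0322; 0.0073 to 0.0819 over the alternatives), and without GV14c or MII14c it did not (0.0743 and 0.0807), and the proteasome list passed with no filter, quantile scaling or the letter c as a term (0.0296, 0.0319 and 0.0364; 0.0296 to 0.113 over the alternatives). Neither passed with an estimated correlation (adjusted p = 0.683 for both with an estimated correlation). Fry, which does not compare members with other genes, called the redox, proteasome and chaperone lists as lower (fry adjusted p = 0.0107, 0.0108 and 0.0497). Of 24 tested redox genes, 12 fell, and CAT and GSR rose. PRDX2, a peroxiredoxin, fell from 2144 ± 513 to 153.8 ± 29.2 RPKM (SD, n = 3; log2 change -3.78 ± 0.24, SE; limma adjusted p = 2.07e-05) and GSTM3, a glutathione transferase, from 4371 ± 774 to 371.6 ± 39.0 RPKM (-3.54 ± 0.21; adjusted p = 1.54e-05). PRDX5 and PRDX4 fell as well (log2 changes -3.58 and -1.89). Of 35 proteasome genes, 13 fell, led by PSMD6, PSMB6, PSMC2 and PSMB7 (log2 changes -3.22, -3.08, -2.73 and -2.53), and PSMA5, PSMC6, PSMD12 and PSME4 rose, while 1 proteasome gene rose without MII15c. Of 26 chaperone genes, 10 fell, among them CCT3 (-3.01 ± 0.27), STIP1 (-2.38 ± 0.44), BAG3 (-1.63 ± 0.29) and DNAJB6 (-1.48 ± 0.28), and HSP90AB1 and HSPA14 rose. The symbols STIP1 and PSMB6 are carried by 3 and 2 genes. Of the chaperones 0 rose in limma without GV14 or MII15c, 1 without GV14c and 5 without MII15. Adjusted over the list alone, 3 chaperones were higher and 11 lower, and the redox and proteasome counts were the same. The risers of these 3 lists were named after their values were seen.

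Regulators of RNA and chromatin went both ways, and camera as planned called none of these lists (adjusted p 0.11 to 0.946). The epigenetic list passed with no filter (adjusted p = 0.0296; 0.0296 to 0.246 over the alternatives), and not with an estimated correlation (adjusted p = 0.722 with an estimated correlation). Of 37 tested genes of polyadenylation and translation control, 7 rose (4 without GV15 or MII15c) and 8 fell. YBX2, an oocyte mRNA-masking protein whose symbol 2 genes carry, fell from 92.41 ± 11.8 to 16.68 ± 1.80 RPKM (SD, n = 3; log2 change -2.40 ± 0.22, SE; limma adjusted p = 7.91e-05), EIF4E1B, an oocyte cap-binding protein, from 116.1 ± 35.6 to 28.87 ± 5.13 (-1.94 ± 0.27), and CPSF3, the cleavage endonuclease, fell by 1.88 on the log2 scale. PABPC1L, a poly(A)-binding protein of oocytes, fell from 3.899 ± 1.49 to 0.208 ± 0.0978 RPKM, and CPEB1 was at 2.292 ± 1.57 and 1.184 ± 0.913 RPKM without passing (adjusted p = 0.355), except with the letter c as a term (0.0328; 0.0328 to 0.965 over the alternatives). Of 46 mRNA decay genes, 9 rose (5 without GV14, 4 without MII15c) and 9 fell, with CNOT6L, a deadenylase, up from 14.83 ± 1.82 to 58.94 ± 17.5 RPKM (1.89 ± 0.27) and TOB1 and EXOSC8 down (log2 changes -2.12 and -1.24). Of 52 splicing genes, 7 rose (2, 3 and 4 without GV14, GV15 or MII15c) and 10 fell, including LSM2, SNRPD2, SNRPC and LSM3 (log2 changes -4.14, -2.89, -2.74 and -2.58). The median of the splicing list was -0.13 as deposited, 0.13 after median-ratio, 0.19 after quantile and 0.01 after TPM scaling, and that of mRNA decay went from -0.05 to 0.19, 0.26 and 0.08. Of 36 epigenetic regulators, 10 rose and 8 fell (3 and 5 without MII15c, and 5 fell without GV14), with UHRF1, a partner of DNMT1, from 66.1 ± 18.5 to 202.7 ± 26.2 RPKM (1.64 ± 0.26), HDAC8 and HDAC3 up by 1.97 and 1.81 on the log2 scale, and PRMT5 down (log2 change -2.37). Of 49 replication and repair genes, 15 rose (7 without MII15c) and 11 fell, and RFC3, RFC5 and RFC4, of the clamp loader, and ORC4, of the origin recognition complex, were among the latter (log2 changes -3.49, -2.48, -1.72 and -1.58). Adjusted over the list alone, higher and lower genes were 6 and 8 for mRNA decay, 6 and 9 for splicing, 11 and 8 for epigenetic regulators and 16 and 11 for replication and repair, with no difference for polyadenylation. Camera and the mean of the list differed in sign for polyadenylation, mRNA decay and splicing.

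Smaller lists had few calls, the same when adjusted over the list alone, and camera called none (adjusted p 0.725 to 0.946). Of 13 tested genes of cyclic nucleotide control of meiotic arrest, AKAP1, NPR2 and ADCY3 fell and PRKAR2A rose (median log2 change 0.07, mean -0.22). ADCY3 lost its call without MII14c or MII15c (limma adjusted p = 0.0572 and 0.0516; 0.00833 to 0.223 over the alternatives), and PRKAR2A without GV14c, GV15, MII14c or MII15c (0.0712, 0.0607, 0.0613 and 0.0731; 0.0065 to 0.164). Both calls were also lost with the replicate block (limma adjusted p = 0.0556 and 0.136). Of 16 fertilisation genes, ZP2, ZP3, ZP4, ORAI1 and STX4, the last named after its value was seen, fell (3 without GV14c or MII15c), with ORAI1, a calcium channel, from 5.061 ± 1.88 to 0.615 ± 0.480 RPKM (limma adjusted p = 0.00412), and ITGB1, an integrin, rose from 50.18 ± 0.477 to 183.6 ± 40.5 RPKM (SD, n = 3; adjusted p = 0.000355). Of 13 transcription factors of embryonic genome activation, TBPL2, an oocyte TBP paralog, fell from 37.96 ± 4.90 to 8.289 ± 5.31 RPKM (adjusted p = 0.00571), and YY1, KLF4 and POU5F1 did not pass (adjusted p = 0.0566, 0.0834 and 0.242). KLF4 and POU5F1 passed as lower without MII15 (adjusted p = 0.0337 and 0.0153; 0.00679 to 0.582 and 0.00204 to 0.596 over the alternatives), and all 3 passed with library weights (0.00233, 0.00679 and 0.00204). YY1 also passed with a mean of at least 5 RPKM (adjusted p = 0.0429; 0.00233 to 0.247 over the alternatives).

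Markers of other cells in the follicle were mostly low. Of 31 cumulus and granulosa markers in the table, 15 stayed under 1 RPKM in every library, and 10 were tested. HAS2, a hyaluronan synthase, VCAN and FDX1 rose, and STAR, a cholesterol carrier of steroid synthesis, NPR2 and CD44 fell. STAR, the highest of them in GV, was at 101.2 ± 34.2 RPKM there and 35.42 ± 5.46 in MII (SD, n = 3; limma adjusted p = 0.00395), and HAS2 went from 16.27 ± 4.06 to 59.54 ± 4.84 RPKM (adjusted p = 0.000685). The call of VCAN was lost without GV14, GV15 or MII15c and with the replicate block (adjusted p = 0.0544, 0.0799, 0.0921 and 0.0746; 0.000585 to 0.128 over the alternatives). With any of these 3 libraries left out in turn 1 marker rose. Camera called neither these markers nor blood markers (adjusted p = 0.856 and 0.236), with a positive direction for the former against a median of -0.55. Cumulus and granulosa counts were the same adjusted over the list alone, and 3 blood markers were then lower. Among blood cell markers CD3E, a T-cell receptor component, fell from 17.92 ± 11.1 to 2.175 ± 1.28 RPKM (adjusted p = 0.0055), while CSF1R and LCP1 were not called (adjusted p = 0.0793 and 0.094). Both passed without MII14c (0.0358 and 0.0315), with library weights (0.0138 and 0.0445) and with the letter c as a term (0.000898 and 0.00601), with ranges of 0.000898 to 0.296 and 0.00601 to 0.351 over the alternatives. Theca and stroma had 1 tested marker, ACTA2, at 6.398 ± 2.40 and 3.818 ± 0.564 RPKM (adjusted p = 0.223). Of 8 tested stress and immediate early genes, GADD45A and BTG2 fell (log2 changes -1.37 and -1.71), and HSPH1 and DUSP6 did not pass. HSPH1 passed without MII14c (adjusted p = 0.0262) and with library weights (0.00392; 0.00392 to 0.321 over the alternatives). Camera did not call this list (adjusted p = 0.509).

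Genes that were higher in MII ended farther beyond their coding sequence. The median 3' UTR distance was 1539 nt (95% bootstrap interval 1456 to 1628) for 1111 higher genes, 610 nt (571 to 646) for 2136 lower genes and 1131 nt (1088 to 1185) for 4655 genes not called. The difference between higher and lower was 929.5 nt, with a two-sided permutation p = 1e-05, the smallest that 100000 resamples give. The resampling behind these intervals and p-values is over genes, which are not independent replicates, so neither measures the spread between libraries. Higher and lower genes each differed from those not called, by 408 and -521.5 nt, with adjusted p = 1e-05 in permutation tests over the 3 comparisons. Coding length went the same way. With genes divided into 4 groups of like size by coding length, 10.4% rose and 41.4% fell in the shortest group, of 63 to 768 nt, and 18.1% rose and 9.7% fell in the longest. Across 8469 genes, which are not independent replicates, Spearman's rho between coding length and log2 change was 0.29. Between 3' UTR distance and log2 change it was 0.26, across 7902 genes. Genes with a 3' UTR distance were divided separately into 4 such groups (129 to 768, 771 to 1272, 1275 to 2067 and from 2070 nt), in which higher genes had median 3' UTR distances of 1513, 1481, 1708 and 1466 nt and lower genes 567.5, 626, 628 and 659 nt.

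**Figure D4:**
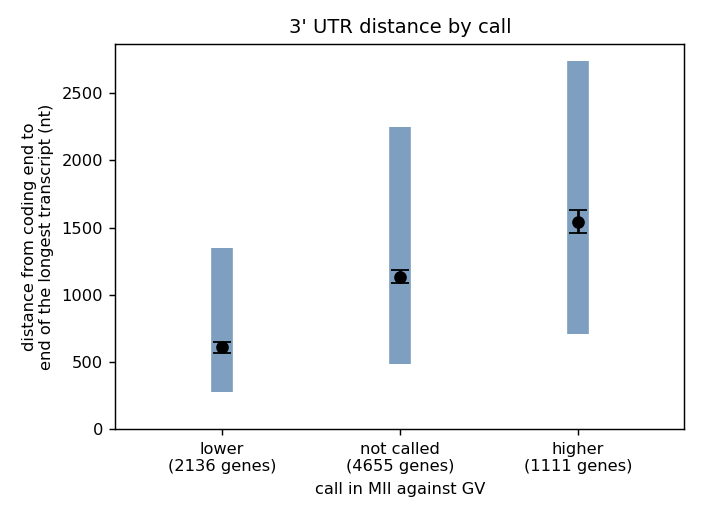
Distance in nucleotides from the coding end to the farthest transcript end (the longest transcript of the axis label), by call in MII against GV. Dots are medians with 95% bootstrap intervals and blue bars are interquartile ranges. The medians are 610 nt for lower, 1131 nt for not called and 1539 nt for higher genes.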

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

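For the patterns in this part, the tests of carried-over somatic cells, of read depth, of genes under 10 RPKM, of coding length, of 3' UTR distance beside coding length and of predicted transcript ends were chosen after the result was seen, and so was leaving quantile normalization out of the test of scaling for the excess of lower genes. The extended annotation holds transcribed regions that enter no comparison above. Of its 6603 predicted genes, 5699 lie clear of annotated genes. They were built from these reads, so their having reads says nothing by itself. Their median is 77 reads, the highest has 21826, and together they hold 4.51% of the 43.89 M supporting reads. These reads are not given per library, so nothing can be said of their stage, and no biological explanation was tested.

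Ribosomal protein and respiratory chain mRNAs were lower in MII, also after median-ratio and quantile scaling, where the least negative list median was -0.85, below the -0.50 set beforehand. Against genes matched on coding length and mean RPKM, members still lay lower, by a median of -0.89 for the less affected list (95% bootstrap interval -1.14 to -0.56), which argues against coding length as the whole cause. With 3' UTR distance matched as well, the respiratory chain still lay lower by -0.99 (-1.43 to -0.75), but only 53 of 73 ribosomal protein genes have such a distance, so for these the test (-0.53, -0.67 to 0.005) is void and transcript length stays open. Cumulus and granulosa cells lost with maturation cannot be told apart from a change in the oocyte, since of 10 tested markers STAR (101.2 to 35.42 RPKM), CD44 (7.03 to 1.80) and NPR2 (2.89 to 0.34) fell while HAS2, FDX1 and VCAN rose, with a median loss of 1.60 RPKM against 61.6 for list members (ratio 0.026, 95% bootstrap interval -0.17 to 0.072), and the median loss over all 31 markers, 0.005 RPKM, is set by the 15 that stayed under 1 RPKM in every library. The blood marker CD3E fell too (17.92 to 2.175 RPKM), and decay of the list mRNAs, or shorter poly(A) tails that weaken priming, stays open as an untested biological hypothesis.

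The excess of genes at least 2-fold lower over genes at least 2-fold higher may rest in part or whole on scaling. The lower share was 75.7% as deposited, 65.1% with TPM, 58.6% with median ratios and 49.5% with quantile normalization. The rule set beforehand took scaling as the cause if either median ratios or quantiles brought the share to a lower bound, and quantiles did. Quantile normalization makes the distributions equal and so largely fixes this share, and it was left out after the result was seen. By median ratios alone the share lies between the bounds and does not decide. Depth argues the other way, since MII libraries held 1.1 times the reads of GV libraries on average. Among genes with a mean of at least 10 RPKM, 67.4% of 2-fold calls were lower (1013 lower, 491 higher; 95% Wilson interval 64.9 to 69.7), which argues against genes near the floor as the whole cause. Genes under 10 RPKM held 1124 lower and 196 higher (85.2%), 928 of the excess of 1450, and for these an effect of the floor cannot be told apart from a loss of mRNA. A true loss of mRNA per oocyte stays open, because RPKM carry no measure of total RNA.

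The longer 3' UTR distance of genes higher in MII held within each of 4 groups by coding length, where the smallest difference was 807 nt (95% bootstrap interval 559 to 1018). It was 818.5 nt among genes with a mean of at least 10 RPKM and 905.5 nt with annotated transcripts alone, so neither low genes nor transcript ends predicted from the reads account for all of it. Introns inside the distance, and any coding exons of other isoforms, were not separated. Log2 change followed coding length about as closely as 3' UTR distance (Spearman's rho 0.29 and 0.26). Whether it followed coding length among genes of like 3' UTR distance was not tested. A dependence on the length of the whole transcript was therefore not separated from one on the 3' UTR. A candidate explanation is that longer 3' UTRs hold more elements that keep or lengthen a poly(A) tail, which needs the genome sequence and was not tested.

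With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 3491 called genes, 2824 of them at least 2-fold, and it alone, 1 of the 10, gave as many by either count. The other 9 splits gave at most 0 by limma's adjusted p, and at most 614 at an unadjusted p under 0.05 against 4228, in the split that parts libraries whose name ends in c from the others. Each of the 9 mixes GV and MII libraries in both groups, so a difference between stages widens their spread. Their low counts are therefore no measure of calls by chance. For gene lists the real split gave 4 by camera, 4 of the 10 splits gave as many, and the highest other gave 5.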

How the results depend on the processing

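No gene called higher or lower reversed its call under any of the 18 alternatives run for genes. All 18 use the same libraries or a part of them, so few reversals could arise. Many calls were lost, however. Of 1162 higher and 2329 lower genes, 580 and 1709 kept the call without MII15c. On the 4 libraries with matching titles and no block, 346 and 1264 kept it. The 3' UTR difference kept its direction, at 738 to 1021 nt, and its permutation p of 1e-05, which resamples genes and not libraries. The fit without a block on 4 libraries, the fit with the letter c as a term and the second form of camera were chosen after seeing the data. Counts of called genes and of called lists that moved by over 1.5 times are given first, and where the alternative's own construction does not show it the cause was not tested. Higher genes were 2133 with quantile normalization and 2262 with library weights, against 1162. Genes at least 2-fold higher were 377 with a pseudocount of 5, 1304 with median ratios, 1555 with quantiles, 1037 with TPM and 1039 with weights, against 687. Genes at least 2-fold lower were 1240 with a pseudocount of 5 and 1380 with a mean of at least 5 RPKM, which tests 5426 genes, against 2137. Leaving out 1 library gave 585 to 1338 higher, 1719 to 2201 lower, 486 to 914 at least 2-fold higher and 1707 to 2124 at least 2-fold lower. Lists called were 8 with no filter, 2 with a mean of at least 5 RPKM and 0 with an estimated correlation (2 at an unadjusted p under 0.05; fry 8), against 4, and 3 to 6 with 1 library left out. Fry called the mRNAs held back until maturation as higher (fry adjusted p = 0.000111). It called the respiratory chain, ribosomal protein, zona, maternal-effect, redox, proteasome and chaperone lists as lower. Ribosomal protein and respiratory chain lists passed camera in all 19 settings with a preset correlation, mRNAs held back until maturation in 18, redox in 12, maternal effect in 6, proteasome in 3, cohesin in 2, and epigenetic and zona lists in 1 each. All 19 share the preset 0.01, below the 0.55 and 0.131 estimated for ribosomal proteins and the respiratory chain. Passing in all of them therefore does not test that assumption. Member counts of lists moved by over 1.5 times as well, and those without 1 library stand with the lists. With weights, higher members were 24 for replication against 15, 15 for decay against 9, 13 for polyadenylation against 7 and 14 for splicing against 7, and lower members 22 for proteasome against 13, 16 for decay against 9 and 17 for splicing against 10. With quantiles, higher members were 14 for decay, 12 for polyadenylation and 11 for splicing, and lower members 3 for fertilisation against 5 and 9 for spindle against 14. With median ratios, lower members were 7 for checkpoint against 12, 5 for epigenetic against 8 and 8 for spindle. The letter c gave 13 lower for maternal effect against 8, and 11 higher and 18 lower for splicing. No filter gave 3 higher for splicing, a mean of at least 5 RPKM 3 lower for fertilisation, and the replicate block 4 higher for polyadenylation. No block on the same 4 libraries gave fewer higher members for checkpoint (6), cohesin (3), replication (4), mRNAs held back (6), epigenetic (3), decay (4), polyadenylation (2), spindle (8) and splicing (3), and fewer lower ones for checkpoint (6), chaperones (5), replication (5), epigenetic (4), fertilisation (2), maternal effect (5), decay (5), redox (7), ribosomal proteins (24) and spindle (7). The difference in detected genes was -1173 at 1 RPKM, -1545 at 0.1 RPKM, -635 at 5 RPKM and -1234 with TPM, with exact p of 0.1, and 0.2 at 5 RPKM. Of 104 named genes called, 86 kept the call under every alternative that tested them, and of 14 not called 10 passed under at least 1. Many were named for a large change or a small p in these same data, so this share does not stand for all calls. MOS and DAZL, not called, changed sign, to 0.01 with quantiles and -0.08 with weights. The title numbers give 2 pairs only, GV14 with MII14c and GV15 with MII15, whose deviations correlated at 0.29 over 8671 genes. A replicate block on these 4 libraries called 895 higher and 2061 lower genes, and no block on the same 4 called 352 and 1280 (339 and 1279 at least 2-fold). The block leaves hardly any residual degrees of freedom, so its calls rest mostly on the variance that eBayes pools over genes. In MII the numbers also part a library with the letter c from one without it. The larger count with the block therefore does not show that the pairs are real. Count models, motif searches and the logistic model with motif terms were not run, since the values are RPKM and no genome was used here. At 1 RPKM a 2 kb gene has 40.4 to 65.1 reads, and whether depth limited the calls of low genes was not tested. The simulated test, which changed few genes, recovered 5% of 2-fold changes over genes of all levels and does not speak to depth.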

Other observations

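All tests in this part were chosen after the result was seen. Among gene families grouped by the stem of the symbol, a grouping made after the lists, 7 of 47 passed limma's camera at the preset correlation. Mitochondrial ribosomal proteins of the MRPL group fell in 30 of 41 tested genes, and MRPL15 rose (median log2 change -1.91; adjusted p = 1.77e-06), and those of the MRPS group fell in 15 of 25, and MRPS16 rose (-1.21; adjusted p = 0.0188). Genes whose symbol begins with COX, subunits and assembly factors of complex IV, fell in 12 of 21 and rose in 0 (-1.85; adjusted p = 0.00047). Of 44 RPL genes 28 fell, and RPL26L1 and the readthrough gene RPL17-C18ORF32 rose (-1.37; adjusted p = 8.77e-06), while of 35 RPS genes 14 fell and RPS3 rose, and that family did not pass (-0.75; adjusted p = 0.111). Centrosomal proteins (CEP) rose in 12 of 27, and CEP19, CEP41 and CEP89 fell (0.63; adjusted p = 0.007), nucleoporins (NUP) rose in 9 of 17, and NUP50 and NUP85 fell (0.80; adjusted p = 0.0188), and ubiquitin-specific proteases (USP) rose in 9 of 35, and USP3, USP10 and USP40 fell (0.41; adjusted p = 0.0214). Members were named after their values were seen. None of the 7 families passed with an estimated correlation (adjusted p = 0.753 to 0.9 with an estimated correlation).

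Libraries whose column name ends in c, 1 GV and 2 MII, lay apart from the others on the second principal component (17% of the variance), at -27.3, -32.8 and -19.9 against 8.8, 32.2 and 39. With the letter as a term beside the stage, limma called 632 genes for the letter, and 1468 higher and 2975 lower in MII. Of the 1162 higher and 2329 lower genes called without the term, 1155 and 2329 remained, while ribosomal protein genes called lower went from 42 to 59 and maternal-effect genes from 8 to 13. What the letter marks is not stated.

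A hypothesis was that mRNAs held back until maturation rise in MII because their tails lengthen and are better captured. The list's members lay above genes matched on coding length, 3' UTR distance and mean RPKM by a median of 0.35 on the log2 scale, with a 95% bootstrap interval of -0.01 to 0.87, and 15 of 22 lay above. The interval spans the 0.30 set as the bound, so it is not settled whether members exceeded matched genes by that much. Even a clear excess could not have shown that tails were the cause, since tail lengths were not measured.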
